A study of Mus musculus with 9 samples.

How the data were processed

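Renal vesicles were captured by laser microdissection from wild-type and Lim1 mutant mouse kidneys at the embryonic stage E12.5. Per the labels, 9 biologically independent samples were made, 5 wild type and 4 mutant, each from about 30 to 50 vesicles. How many embryos or litters went into a sample is not given in the sources used here. RNA was amplified in 2 rounds and labelled with biotin, per the labels' protocols, and hybridised to an Affymetrix array of 45101 probe sets. The authors deposited 1 intensity value per probe set and array on a linear scale. The intensities came from the Affymetrix GCOS software, per the submitters' processing notes. The algorithm within it, its version and its scaling target are not given in the sources used here. In the deposited values, the mean after removing the lowest and highest 2% of probe sets was 1500 on each of the 9 arrays, so each array had been scaled to a common level before deposit. Amplification over 2 rounds favours the 3 prime end of transcripts, and a probe set far from that end can read low whatever the level of the gene.

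Probe sets were named through the platform annotation. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none. Probe sets with several symbols were given no gene name. No genome sequence and no probe coordinates were used here, so probe sets are identified by name and by gene only. The RefSeq gene order (GRCm38.p6) served only to find the neighbours of Lhx1 and the chromosomes of the called genes. Pax2 was not analysed here, and Cited1 lay below the filter on dim probe sets.

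The design was fixed before the data were examined: the fit, the filter, the gene lists, the rule for named genes and most of the alternatives. Intensities were transformed as log2(value + 42.41), where 42.41 is the 25th percentile of all values. Differences on this scale understate the change of dim probe sets. The log2 medians of the arrays ranged from 7.54 to 7.89, a range of 0.349 that exceeded the tolerance of 0.1, and the arrays were therefore quantile normalised, as the design required. Control probe sets, 64 in all, were not tested. Of the other 45037 probe sets, the 27022 whose mean lay at or above the 40th percentile were tested. The mutant minus wild-type difference was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), with group as the only term. P values were adjusted over the 27022 probe sets by the Benjamini-Hochberg method at 0.05. Adjusted p values below are from limma unless another test is named. Signals are given as deposited, as mean ± SD, and log2 differences with their standard errors. The number of arrays limits the precision of each value. A gene was represented by its probe set with the highest mean, which gave 13226 genes. Single values were compared by exact permutation tests over the 126 splits of the arrays, two-sided, where the smallest possible p is 0.00794.

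The named genes were Lhx1, up to 12 genes per direction with the largest difference among those past the threshold with no overlap between the groups, and, where a direction had fewer, the genes with the lowest p and no overlap, up to 6. Members of a list that passed over all probe sets or over the list alone were added, at most 4 per list and direction. Also named were Pou3f3, Dll1, Jag1, Pax8, Wnt4, Fgf8, Cdh6 and Six2, whatever their result. A called probe set that was not the one representing its gene is named as such.

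Of 25 gene lists, 24 were tested with camera from limma on the gene-level values, with a preset correlation between genes of 0.01 and adjustment over the 24 lists. They covered renal vesicle regulators, the Notch pathway, cap mesenchyme, Wnt and beta-catenin targets, the FGF response, epithelialisation, podocyte, tubule, ureteric bud, stroma, endothelium, erythroid cells, macrophages, neural cells, adrenal and gonad, the cell cycle, p53 and apoptosis, immediate early and stress genes, hypoxia and glycolysis, matrix and integrins, LIM homeodomain factors and cofactors, BMP and TGF-beta, retinoid signalling and Hox genes. Sex-linked genes, of which 3 were measured, were given as values. Some genes stood in more than 1 list. Camera was also run with the correlation estimated per list, and fry as another test. The level of a list on an array is the median over its members of the deviation from each gene's mean over the 9 arrays.

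The fit was checked on simulated arrays of 4 against 5 with 27022 probe sets. Of 50 probe sets changed by a log2 difference of 1, the test recovered 3. It recovered 16 of 50 at a difference of 2, 33 of 50 at 3 and 33 of 50 at 4, with 2 false calls among 87. In the same check, 4 of 4 lists of 15 genes shifted by 1 were called, and no unshifted list was. The simulated genes varied independently of each other, so the check says nothing about false calls for lists whose genes move together. Alternatives covered the normalisation, the filter, the pseudocount, the variance model, array weights, the replicate number as a block, each array left out in turn, the threshold, the averaging of probe sets and other list tests. An alternative without wild-type arrays 1 and 3, and the estimated correlation within alternatives where a further list passed, were added after the data were seen.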

Results

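The renal vesicle is the first epithelial stage of the nephron, and its proximal and distal parts later give rise to podocytes and tubule segments. Lim1, now named Lhx1, encodes a LIM homeodomain transcription factor of the early nephron. The series compared gene expression in vesicles captured from wild-type kidneys (5 arrays) and from Lim1 mutant kidneys (4 arrays) at the embryonic stage E12.5. Each array gave signals for 45101 probe sets, with array medians between 144 and 195. Pairs of arrays correlated at r of 0.748 to 0.886 within the wild type, 0.848 to 0.895 within the mutants and 0.775 to 0.912 between the groups, on the log2 scale across probe sets, which are not independent replicates. Wild-type arrays 3 and 1 stood apart most, with mean correlations with the other arrays of 0.783 and 0.802, against 0.826 to 0.864 for the rest. The first principal component, with 21.1% of the variance, separated wild-type array 3, and the second, with 18.6%, separated wild-type array 1.

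The mutated gene was examined first, and its 2 probe sets gave different results. At the dimmer probe set the Lhx1 signal was 6544 ± 6261 in the wild type (SD, n = 5) and 8.61 ± 1.99 in the mutants (n = 4), a log2 difference of -6.64 ± 0.57 (adjusted p = 0.00329). Each of the 4 mutants, at 6.88 to 10.5, lay below the lowest wild-type array at 2327, and the exact permutation p was 0.00794, the smallest that 126 splits can give. At the brighter probe set, which represents the gene in the lists, the signal was 10690 ± 6556 in the wild type and 4499 ± 347 in the mutants, a log2 difference of -0.86 ± 0.58 (adjusted p = 0.833, exact permutation p = 0.262). Mutant signals there ranged from 4108 to 4951, and wild-type array 3 read 1696. The labels do not say which part of the gene was altered, so only a probe set inside that part checks the genotype, and which of the 2 that is remains unknown here.

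Few other probe sets passed the test, which in simulation recovered 3 of 50 changes at a log2 difference of 1 and 16 of 50 at 2. The number that passed therefore does not show how many genes changed. Of 27022 probe sets tested, 9 passed adjusted p 0.05, 4 higher and 5 lower in the mutants, and at all 9 the mutant arrays lay entirely on 1 side of the wild-type arrays. Groups did not overlap at 609 probe sets, or 2.25% of those tested, where chance gives 1.59%. An unadjusted p under 0.05 was reached by 1803 probe sets, 6.67% of those tested, where chance gives 5%.

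The genes that fell besides Lhx1 (its dimmer probe set) were Cadps2, Kif26a, Cldn5 and 4930523C07Rik. Cadps2, which encodes an activator of regulated vesicle secretion, went from 3782 ± 1630 in the wild type to 72.0 ± 82.4 in the mutants (log2 difference -5.26 ± 0.53, adjusted p = 0.00576). Kif26a, an atypical kinesin, went from 2030 ± 1141 to 76.5 ± 42.3 (-4.06 ± 0.50, adjusted p = 0.0236). Cldn5, a claudin of tight junctions best known from endothelium, went from 9595 ± 1077 to 932 ± 325 (-3.40 ± 0.32, adjusted p = 0.0045), and no wild-type array read below 7988 or mutant above 1329. 4930523C07Rik, a gene known only by its clone name, went from 2130 ± 826 to 170 ± 42.3 (-3.32 ± 0.43, adjusted p = 0.0273), and its other 2 tested probe sets had differences of -2.83 and -3.17 (adjusted p = 0.304 and 0.73). At the latter the groups overlapped, with 19.5 and 7.4 on wild-type arrays 3 and 5 and 8.2 to 57.2 on the mutant arrays.

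The genes that rose were Irf4, Tacr3, Gpx6 and Igf2. Irf4, a transcription factor best known from lymphoid cells, went from 14.0 ± 5.05 in the wild type to 813 ± 537 in the mutants (log2 difference 3.69 ± 0.43, adjusted p = 0.0171). Its other probe set lay below the filter, at 107 in the wild type and 90.2 in the mutants. Tacr3, the receptor for neurokinin B, went from 28.8 ± 30.8 to 661 ± 192 at 1 of its 3 probe sets (3.29 ± 0.41, adjusted p = 0.0236), which is not the one representing the gene. The other 2 Tacr3 probe sets disagreed, at 1.65 and -1.06. Gpx6, a member of the glutathione peroxidase family, went from 685 ± 178 to 4265 ± 628 (2.60 ± 0.36, adjusted p = 0.0383). Igf2, the imprinted fetal growth factor, was abundant in both groups and went from 24970 ± 4617 to 54890 ± 6917 (1.16 ± 0.15, adjusted p = 0.0236). Its other probe set lay below the filter, at 147 in the wild type and 87.4 in the mutants, and did not show the rise.

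**Figure D1:**
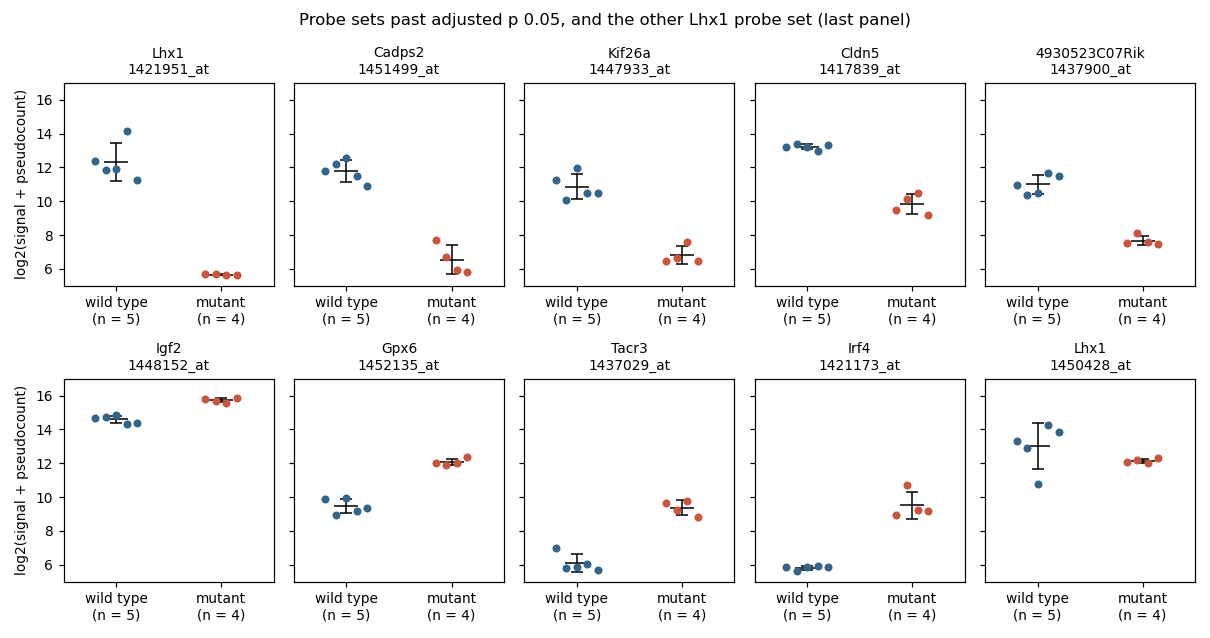
Signal of the 9 probe sets past adjusted p 0.05 and of the brighter Lhx1 probe set (last panel) in 5 wild-type (blue) and 4 mutant (red) arrays, as quantile normalised log2(signal + pseudocount); points are arrays, horizontal bars group means and whiskers SD. At the 9 probe sets the groups do not overlap, while at the brighter Lhx1 probe set the mutants lie within the wild-type range.

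With each array left out in turn, 3 to 8 probe sets passed, and Lhx1 (dimmer probe set), Cldn5 and Cadps2 were the 3 of the 9 that passed in each of these 9 fits. Irf4 passed in 4 of them, and the other 5 called probe sets in 1 each. Without wild-type arrays 1 and 3 none passed in limma (2003 at an unadjusted p under 0.05), with adjusted p of 0.0567 for these 3, and the Igf2 call was also lost without quantile normalisation (adjusted p = 0.12), without a variance trend (adjusted p = 0.485) and with median centring (adjusted p = 0.378, with 3 higher and 6 lower among 9 calls). The Tacr3 and Gpx6 calls were lost without the filter (adjusted p = 0.0551 for both), and the Irf4 call with the pseudocount at the median (adjusted p = 0.0545). With the pseudocount at the 10th percentile and at the median, the Irf4 difference was 4.74 and 2.25. That of the called Tacr3 probe set was 4.16 and 2.01.

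Next in rank among genes without overlap, though not past the threshold, were Hs3st3b1, a heparan sulfate sulfotransferase, and Myo5b, a myosin of vesicle transport, both lower in the mutants (log2 differences -3.65 ± 0.54 and -2.11 ± 0.32). Bmf, a BH3-only member of the Bcl-2 family, had a difference of 2.33 ± 0.35. The adjusted p of all 3 was 0.0576, and with array weights Hs3st3b1 and Myo5b passed (adjusted p = 0.0349 for both). C1qtnf12 followed at 0.79 ± 0.13 (adjusted p = 0.149) and Cetn4, a centrin, at 2.75 ± 0.51 (adjusted p = 0.23). The other tested probe sets of C1qtnf12 were also higher, at 0.72, 1.40 and 1.84 (adjusted p = 0.696, 0.236 and 0.329). The other tested probe sets of Hs3st3b1 did not share its difference, with values of -0.06 and 0.47.

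Known regulators of the renal vesicle did not pass the test as a group. Of 23 measured members, 11 had differences above 0 and 12 below, none passed over all probe sets or adjusted over the list alone, and the list had a median of -0.32 (camera adjusted p = 0.0957, and 0.673 with an estimated correlation). Lhx1 is a member, represented by its brighter probe set and not by the dimmer probe set that passed. The list passed without wild-type array 3 (adjusted p = 0.00374) and without wild-type array 2 (adjusted p = 0.0186), though not with an estimated correlation (adjusted p = 0.428 and 0.537). Dll1, a Notch ligand of the distal vesicle, had signals of 9593 ± 6284 and 3368 ± 1141 (log2 difference -1.33 ± 0.48, adjusted p = 0.696). Jag1, another Notch ligand, had a difference of -0.52 ± 0.21 (adjusted p = 0.73), Pax8, a paired-box factor of the early nephron, one of -0.63 ± 0.35 (adjusted p = 0.795), and Pou3f3, a POU factor of the distal nephron, one of -0.64 ± 0.52 (adjusted p = 0.867). Wnt4, the signal that drives vesicle formation, was at 28140 ± 13390 and 27890 ± 11980 (0.10 ± 0.39, adjusted p = 0.981), although its other probe set read 0.82. Fgf8 had a difference of 0.35 ± 0.55 (adjusted p = 0.94) and Cdh6, a cadherin of the vesicle, one of 0.14 ± 0.31 (adjusted p = 0.958, with -0.21 at its other probe set). Six2, the marker of the cap mesenchyme from which vesicles form, was at 996 ± 117 and 2018 ± 868 (0.88 ± 0.40, adjusted p = 0.748).

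Genes of the tubule were lower in the mutants as a list. Of 13 measured members, 11 had differences below 0 and 2 above, with a median of -0.57 (camera adjusted p = 0.000371). The adjusted p = 0.0748 with an estimated correlation. No member passed over all probe sets with all arrays, and adjusted over the list alone 3 fell and 1 rose. Without wild-type array 1, Tfap2b passed over all probe sets (-3.19, adjusted p = 0.0177). Those that fell were transcription factors: Sim1 (log2 difference -3.37 ± 0.83), Tfap2b (-2.53 ± 0.67) and Mecom (-2.25 ± 0.48, from 6694 ± 2457 to 1499 ± 717). Cdh2, the N-cadherin of proximal tubule cells, rose by 1.07 ± 0.34. The other tested probe set of Sim1 read -0.59 and that of Mecom -0.58. The transporters and endocytic receptor of the list were dim, such as Slc34a1 at 161 and 118 and Lrp2 at 194 and 178. The level of the list was -1.20 to -0.42 on the mutant arrays and -0.12 to 0.74 on the wild-type arrays.

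**Figure D2:**
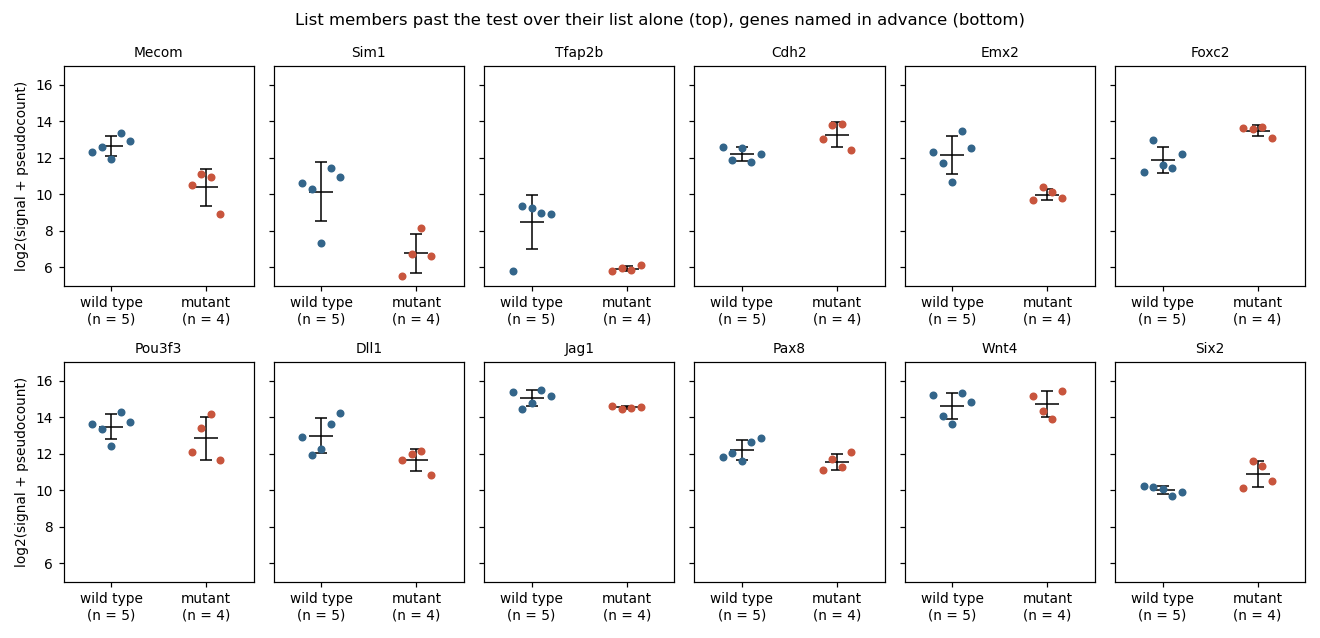
Signal of 6 members that passed over their list alone (top; Mecom, Sim1, Tfap2b and Cdh2 of the tubule list, Emx2 of the ureteric bud list, Foxc2 of the podocyte list) and of 6 genes named in advance (bottom) in 5 wild-type (blue) and 4 mutant (red) arrays, as quantile normalised log2(signal + pseudocount); points are arrays, horizontal bars group means and whiskers SD. Mecom, Emx2 and Foxc2 show no overlap between groups, and wild-type array 1 lies with the mutants for Tfap2b.

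Podocyte genes did not pass as a list (12 measured, 7 above 0 and 5 below, median 0.30, adjusted p = 0.182), except with probe sets averaged per gene (adjusted p = 0.0484, and 0.285 with an estimated correlation). Adjusted over the list alone, 1 member rose and none fell, and no member passed over all probe sets. The member that rose was Foxc2, a forkhead factor of early podocytes and of mesenchyme, from 4217 ± 2412 to 11610 ± 2190 (log2 difference 1.59 ± 0.36). Nphs1, the slit diaphragm protein of differentiated podocytes, was dim in both groups, at 96.7 and 153.

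Markers of neighbouring cell types were also compared, since captured tissue can include them. Of 17 measured ureteric bud genes, 14 had differences below 0 and 3 above, with a median of -0.81 (camera adjusted p = 0.00324). That list had an adjusted p = 0.445 with an estimated correlation. No bud gene passed over all probe sets and 1 fell adjusted over the list alone, Emx2, a homeobox factor known from the bud and from early nephron epithelia, from 5431 ± 3555 to 1007 ± 174 (log2 difference -2.16 ± 0.50). Ret, the receptor of the bud tip, had signals of 2648 and 199 (-2.43 ± 1.26) and Calb1, a calcium-binding protein of the bud, 10040 and 1137 (-2.21 ± 1.15). Ret and Calb1 were chosen after their values were seen. Wild-type arrays 3 and 2 had the highest levels of the list, 0.94 and 0.80, while wild-type arrays 4 and 1 were at -0.49 and -0.06, within the mutant range of -0.54 to 0.01.

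All 15 measured endothelial genes had differences below 0, with a median of -0.65 (camera adjusted p = 3.3e-05). The adjusted p was 0.445 with an estimated correlation. Cldn5 was the 1 member that fell, both over all probe sets and adjusted over the list alone. Others such as Kdr (-1.24 ± 0.93), Erg (-1.42 ± 0.95) and Egfl7 (-0.57 ± 0.44) did not pass, and they too were chosen after their values were seen. The list stood highest on wild-type arrays 3 and 4, at 1.36 and 0.93, and wild-type array 5 was at -0.58, against -0.67 to 0.03 on the mutant arrays. Of 10 measured neural genes, 9 were below 0, with a median of -0.69 (adjusted p = 0.00872). None passed over all probe sets or adjusted over the list alone, and the list had an adjusted p = 0.474 with an estimated correlation. Wild-type array 3 set this result, with a level of 1.55 against -0.47 to 0.17 on the other 8 arrays, and without it the adjusted p was 0.21. With array weights the neural list did not pass either (camera adjusted p = 0.0639). Of 100 splits of the 9 arrays, the real one included, 25 shifted at least as many lists as the 4 found here.

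The remaining lists did not pass the test. No member of theirs, at the probe set representing its gene, passed over all probe sets or adjusted over the list alone. Cap mesenchyme genes had a median of 0.33 over 19 genes (adjusted p = 0.509), stroma -0.11 over 23 (adjusted p = 0.946), erythroid genes -0.31 over 9 (adjusted p = 0.157), macrophage genes 0.39 over 13 (adjusted p = 0.507) and adrenal and gonad genes -0.19 over 9 (adjusted p = 0.61). Wild-type array 3 had the highest level of the stroma, macrophage and erythroid lists, at 1.97, 1.05 and 0.59. Without that array, macrophage genes passed as higher and hypoxia and glycolysis genes as lower (adjusted p = 0.0272 for both, and 0.482 and 0.428 with an estimated correlation). The hypoxia and glycolysis list also passed without wild-type array 5 (adjusted p = 0.0417, and 0.543 with an estimated correlation), and erythroid genes passed as lower without mutant array 2 (adjusted p = 0.033, and 0.55 with an estimated correlation). With all arrays, the hypoxia and glycolysis list had a median of -0.22 over 21 genes (adjusted p = 0.0957).

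Among the signalling lists, the Notch pathway had a median of 0.07 over 26 genes (adjusted p = 0.628), Wnt and beta-catenin targets 0.11 over 17 (adjusted p = 0.61), the FGF response -0.14 over 16 (adjusted p = 0.484), BMP and TGF-beta genes 0.28 over 24 (adjusted p = 0.182) and retinoid genes 0.32 over 15 (adjusted p = 0.622). LIM homeodomain factors and cofactors had a median of -0.17 over 16 genes (adjusted p = 0.413) and Hox genes 0.18 over 24 (adjusted p = 0.478). Lhx1 stood in the LIM list too, again through its brighter probe set only. Epithelialisation genes were at 0.03 over 30 (adjusted p = 0.781), matrix and integrin genes at 0.07 over 28 (adjusted p = 0.946), cell cycle genes at 0.03 over 29 (adjusted p = 0.509), p53 and apoptosis genes at 0.35 over 15 (adjusted p = 0.484), and immediate early and stress genes at 0.08 over 18 (adjusted p = 0.946). For the Notch, epithelialisation and immediate early lists the test pointed down although the median lay above 0, and the mean of the Notch list was -0.03.

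**Figure D3:**
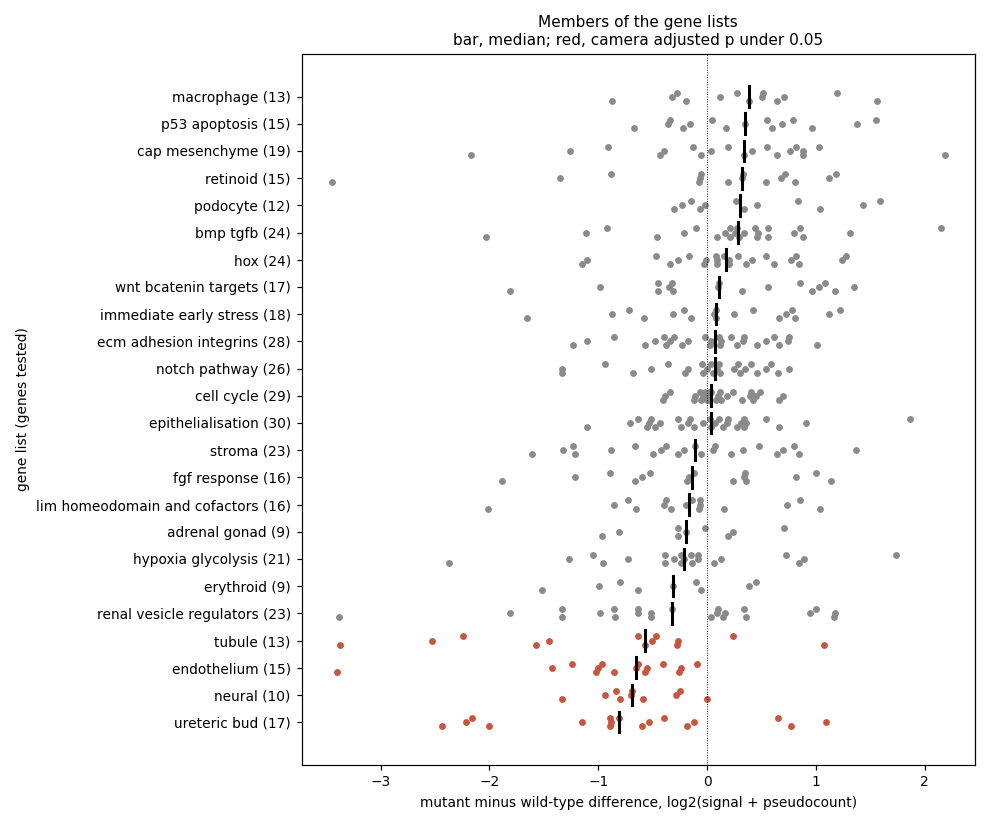
Mutant minus wild-type difference of each measured member of the 24 tested gene lists, on the log2(signal + pseudocount) scale; each point is a gene, black bars are list medians, numbers beside the names are genes tested and red marks lists past camera adjusted p 0.05 with the preset correlation. The 4 red lists, tubule, endothelium, neural and ureteric bud, have medians of -0.57, -0.65, -0.69 and -0.81.

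Control probe sets gave a measure of transcript length after amplification. The 3 prime to 5 prime signal ratio of Gapdh was 38.1 ± 29.1 in the wild type (SD, n = 5) and 34.2 ± 20.9 in the mutants (n = 4; exact permutation p = 0.921), and that of beta-actin was 17.1 ± 2.92 and 20.5 ± 4.38 (exact permutation p = 0.19). The highest Gapdh ratio, 87.6, was on wild-type array 3. Sex-linked genes differed between arrays of the same group. On mutant array 4 the main Xist probe set read 182, against 41920 to 60040 on the other mutants and 32170 to 91630 on the wild-type arrays. Eif2s3y, on the Y chromosome, read 4175 on mutant array 4, 1743 on wild-type array 4 and 507 on wild-type array 5, and at most 122 on the other 6 arrays. Kdm5d, also on the Y chromosome, read 900, 414 and 326 on wild-type arrays 5 and 4 and mutant array 4 at one of its probe sets, and at most 75.4 on the other arrays. At the probe set representing the gene its means were 152 in the wild type and 139 in the mutants. Without mutant array 4, 3 probe sets passed.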

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

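Among the tests below, the 3 on the Lhx1 probe sets, the test on the other endothelial genes, the endothelium list without Cldn5, the count of other splits for the genes changed, the tests with covariates and the permutations of list means were chosen after the result was seen.

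Within 68 groups of values, 7 held an array far from the rest of its group by Dixon's test, where chance gives about 3.4 (about 1 group in 20). Mutant array 2 had an Irf4 signal of 1616, against 507 to 606 on the other mutants. Mutant array 3 had a Kif26a signal of 140, against 49.2 to 59.6. Wild-type array 1 read 83.0 for the called Tacr3 probe set, against 8.32 to 22.9 on the other wild-type arrays, and 14.5 for Tfap2b, against 397 to 669. Wild-type array 3 had a Sim1 signal of 114, against 1281 to 2813. Mutant array 4 had an Xist signal of 182, against 41920 to 60040, and an Eif2s3y signal of 4175, against 3.84 to 21.2.

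Of 100 splits of the 9 arrays into 5 and 4, drawn at random with the real split included, 1 called as many probe sets as the real one: it called 9, and the highest of the others called 6. Chance alone is therefore unlikely for that count as a whole, Lhx1 included, at the 0.05 level. The splits do not exclude chance for any single call. For the gene lists, 25 of the 100 splits shifted at least as many lists as the 4 of the real split, and the highest of the others shifted 8, so chance cannot be excluded.

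The Lhx1 probe sets disagreed, with a near total loss at the dimmer one and 42.1% of the wild-type mean signal left at the brighter one. Wild-type vesicles among the mutant captures are argued against: that share of the lowest wild-type signal would give 980 at the dimmer probe set, which is at least 81.5 times what the mutants read, since all 4 lay below the 10th percentile of all values. A fixed background at the brighter probe set could hold the mutants near 4499, but 1 wild-type array (array 3, at 1696) read below all mutants, which is too few to decide. A transcript kept outside the altered part of the gene may equally leave the 42.1%, and it cannot be told apart from background because the labels do not place the alteration.

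The tubule list was lower in the mutants (median -0.57), and a trend that follows the beta-actin 3 prime to 5 prime ratio is argued against as the whole cause: with that ratio of the quantile normalised signals as a covariate all probe sets moved by a median of 0.342, yet the list kept a camera p = 0.000278, a median of -1.01 and a permutation p = 0.00794 for its mean. This rests on that ratio differing between groups on the scale of the fit (exact permutation p = 0.0397), a condition set after the values were seen, and 2 of the 4 conditions tried, which required it on the deposited scale too or alone (exact permutation p = 0.19), left this open. Longer or better preserved RNA that the Gapdh ratio tracks stays open: the list kept a camera p = 0.000119 (permutation p of its mean 0.0397), but the ratio hardly differed (exact permutation p = 0.921) and moved probe sets by a median of 0.0145, so the bound set in advance, a p under 0.05, could not decide. Ureteric bud cells in the wild-type captures could have added to the tubule difference. The 5 measured core bud markers had a median of -0.88, from -2.43 for Ret to 0.77 for Wnt11. Their mean differed by -1.03 (exact permutation p = 0.175). With that mean as a covariate, the tubule mean had a permutation p = 0.00794, the smallest possible (camera p = 1.37e-05, median -0.80). The levels per array, compared after they were seen, argue against such cells as the whole cause. Wild-type arrays 4 and 1, with bud levels of -0.49 and -0.06 within the mutant range, had tubule levels of 0.74 and 0.45. The mutant tubule levels were -1.20 to -0.42. Wild-type arrays 3 and 2, highest for the bud list (0.94 and 0.80), had the lowest wild-type tubule levels (-0.12 and -0.055). Whether such cells were a part of the cause stays open. A difference set by the genotype also stays open, and chance was not excluded for the lists.

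Cldn5 was lower by 3.40 on the log2 scale while the rest of the endothelium list was less so. The levels per array, compared after they were seen, argue against fewer endothelial cells in the mutant captures as the whole cause. Over the wild-type arrays the endothelium level ran from -0.58 to 1.36, while Cldn5 stayed at 7988 to 10630. Wild-type array 5 had the lowest of these levels and the highest Cldn5 signal. The mutants, with levels of -0.67 to 0.03, read 609 to 1329. Whether such cells were a part of the cause stays open. The other 10 well measured endothelial genes had a median of -0.56, and each fell less than Cldn5, from -1.42 ± 0.95 for Erg to -0.096 ± 0.43 for Ramp2. A 97.9% interval of their median, -1.24 to -0.24, lies above -1.70, the midpoint between no change and the Cldn5 difference. That interval runs over genes taken as independent and leaves out the spread between arrays, so it cannot decide (estimated correlation of the full list 0.29). The most abundant of them, Ramp2 and Egfl7, went from 5075 to 4199 and from 3584 to 2135. Larger falls in mean signal were seen for Kdr (1818 to 504), Erg (626 to 112) and Emcn (597 to 174). Without Cldn5 the list had p = 0.00014 with the preset correlation and 0.124 with an estimated one, so whether endothelial cells also differed cannot be told apart from genes moving together between arrays. An effect of the mutation on Cldn5 outside endothelium also stays open and was not tested.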

How the results depend on the processing

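Leaving out wild-type arrays 1 and 3 together, the tests with covariates or without Cldn5, the estimated correlation within alternatives, and the exact permutation of list means were chosen after the data were seen. The count of 9 changed probe sets stayed at 7 to 12 across scalings, filters, pseudocounts, variance models, array weights, gene means and a minimum log2 difference of 1; it was 14 at adjusted p 0.1, 3 to 8 with 1 array left out and 0 without wild-type arrays 1 and 3 (limma, with 2003 probe sets at an unadjusted p under 0.05), where fewer arrays were fitted. With the replicate block 0 passed (limma, with 1756 at an unadjusted p under 0.05). The labels do not say whether same-numbered samples are paired, and their deviations from the group means correlated weakly (-0.105 to 0.0537). The dimmer Lhx1 probe set kept its direction throughout, at -6.91 with the replicate block (adjusted p = 0.0715) and -6.75 without wild-type arrays 1 and 3 (adjusted p = 0.0567), and with 1 array left out its adjusted p was 0.00117 to 0.0182. The size of its difference depended on the pseudocount, at -7.96 with the 10th percentile and -4.88 with the median. Lists past the threshold numbered 3 to 6 over the scalings, filters, pseudocounts, weights, block and arrays left out, but 0 with an estimated correlation (2 lists at an unadjusted p under 0.05), 0 by fry in 1 direction (3 lists; 9 passed its mixed test, which counts changes either way and does not compare with other genes) and 0 by exact permutation of list means (1 list, tubule, p = 0.0159; adjusted p = 0.343); the cause was not tested, though 126 splits cannot give a single list an adjusted p under 0.05. The robust variance model does not enter camera, so it gives lists no separate value. The beta-actin ratio difference, 0.25 on the log2 scale, became 0.32 with quantile normalisation (exact permutation p = 0.0397). With 1 array left out it ranged from 0.14 to 0.35 as deposited, and that of Gapdh, -0.06, from -0.41 to 0.31. Wnt4 (0.10) turned to -0.0593 with median centring and -0.0258 without wild-type arrays 1 and 3, and ranged from -0.14 to 0.36 with 1 array left out; Cdh6 (0.14) turned to -0.0818 without those arrays and ranged from -0.0607 to 0.31. With 1 array left out the brighter Lhx1 probe set (-0.86) ranged from -1.42 to -0.55, Pou3f3 (-0.64) from -1.09 to -0.24 and Fgf8 (0.35) from 0.0497 to 0.63; the cause was not tested. Over 27 named gene results and their alternatives, 452 of 536 values kept direction and side of the threshold, 67 lost and 9 gained the threshold, and 8 changed sign. The median of all probe sets, 0.034, moved by 0.0372 to 0.0712 as deposited and by -0.0607 to -0.0267 with median centring. With the beta-actin ratio as a covariate the tubule median was -1.02, and -1.01 with the quantile normalised ratio. Dim probe sets limit the rest, since a signal near the pseudocount of 42.41 hides falls below it.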

Other observations

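The tests of gene families grouped by name, the count of called genes on the Lhx1 chromosome and the permutation of the imprinted genes' mean were chosen after the data were seen. The families added no further shift: of 16 tested with camera, none passed in either direction. The forkhead factors came nearest, with 17 of 23 measured genes above 0 and a median of 0.45 (adjusted p = 0.0753, and 0.772 with an estimated correlation); the median was 0.43 without quantile normalisation and 0.34 with median centring. The Sox factors had 10 of 14 genes below 0 (median -0.33, adjusted p = 0.365). Cytochrome c oxidase genes had 13 of 15 above 0 (median 0.22, adjusted p = 0.296). Collagens, claudins and cytosolic ribosomal proteins had medians of 0.01, -0.02 and -0.02. In the Wnt pathway, Dkk1, a secreted inhibitor singled out after its values were seen, was lower at both of its probe sets, with log2 differences of -3.09 ± 0.65 (adjusted p = 0.329) and -1.81 ± 0.56 (adjusted p = 0.651), neither past the threshold.

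Because Igf2 is imprinted, other imprinted genes might have risen with it. The test showed no joint rise: 20 measured imprinted genes without Igf2 split 10 above 0 and 10 below, with a median of 0.02 (95.9% interval over genes, not arrays, -0.09 to 0.16, against 1.16 for Igf2), camera gave p = 0.652 and pointed down, and the mean differed by 0.06 (exact permutation p = 0.659). The list was not split by the parental copy expressed, so moves in opposite directions would cancel in it. Dlk1 (1.37 ± 0.71) and Airn (-1.84 ± 0.57) were the members farthest from 0.

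Several called probe sets were near all or none between groups, so a chromosomal stretch around Lhx1 that differs between mutant and wild-type mice could carry some of them. This is argued against, since 0 of the other 8 called genes lie on the chromosome of Lhx1. Among the 100 nearest tested neighbours of Lhx1 in the RefSeq order (GRCm38.p6), 2 had an unadjusted p under 0.01, or 2%, against 1.91% of the other genes (Fisher's exact p = 0.717). These were Lhx1os, which neighbours Lhx1, and Tmem98, with log2 differences of 1.07 ± 0.33 and 0.88 ± 0.22.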
